A study of Mus musculus with 8 samples.

How the data were processed

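The deposited data are 1 table of raw UMI counts for 16249 genes and 62599 cells from 8 libraries. According to the labels, cardiac interstitial cells of C57BL/6 mice were isolated on a Langendorff setup 24 h or 12 weeks after myocardial infarction, from control hearts or hearts given the drug, and run on 10x Chromium version 3 chemistry. The series title names the drug as MCB-613, a stimulator of steroid receptor coactivators, and the sample labels call the arms only control and drug. Each time and arm has 2 hearts, collected and sequenced separately per the design text, so n = 2 hearts per group and 4 groups. Per the submitters' processing notes the authors used Cell Ranger, Seurat 3 and the mm10 build. The Cell Ranger version is not given in the sources used here. In the deposited counts a gene has either no count in a library or counts in at least 10 cells of it, so a 0 can stand for a few cells.

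All cells were taken into 1 analysis, and no column of the table was left out. Cells with fewer than 200 genes or over 20% mitochondrial UMIs were removed (106 cells). Doublet scores came from the Scrublet function of scanpy 1.11.5. In each library the cells with the highest scores, 0.8% for each 1000 cells, were left out (5350 cells), which leaves 57143 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen by library were scaled with a limit of 10. Genes seen in fewer than 10 cells were left out of this step. Clusters came from 30 principal components, 15 neighbours and Leiden clustering at resolution 1, with no batch correction, which gave 28 clusters. A cluster received a class name from 18 fixed marker lists when at least 3 markers of that class were among its 50 top genes by fold, detected in at least 20% of its cells, with a pseudocount of 0.05. No other class could hold more markers among its top 10 genes. Clusters with no such match stayed unnamed. Class names here mean cells with these markers, and the text calls them by the class name for short. The class of monocytes or macrophages is called macrophages, and monocytes are not separated from it.

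Counts were summed per library and class, and a library entered a class with at least 20 cells. Genes were tested in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3: filterByExpr by group, TMM scaling, a robust quasi-likelihood fit of 4 group means without a replicate block, and Benjamini-Hochberg adjustment with a threshold of 0.05 within each class and contrast. The contrasts are drug minus control at 24 h, drug minus control at 12 weeks, the difference between these 2 effects, and control at 12 weeks minus control at 24 h. Errors given after ± are standard errors of the log2 change, taken as its absolute size over the square root of F, unless SD is named. CPM values are counts of the class scaled to its TMM-adjusted total in a library (cpm in edgeR). Where both libraries of a group have 0 counts, no fold is given, since a 0 can stand for up to 9 cells in each library. A list with such a gene also has its median with 18 counts for a group at 0 (9 cells in each of 2 libraries at 1 UMI per cell), given where it differs; a cell can hold more than 1 UMI, so this is no bound. Low counts are raised by a prior count of 2 only in the correlations between libraries of the same number.

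Before the data were examined, 27 gene lists, the marker lists, the tests, the alternatives and the rule for named genes were fixed. Lists were tested with camera at a preset correlation of 0.01, among the lists with at least 5 tested members, which were 25 in each class. A list is called higher or lower in the direction of this test, and its median log2 change over members stands beside it. The same lists were run with a correlation estimated from the data and with fry. With the estimated correlation 0 of 25 lists passed in any class or contrast. With fry 12, 19 and 10 passed in the time contrast in fibroblasts, macrophages and endothelial cells. In the drug contrasts fry called 1 list, in macrophages at 24 h. Every list call below is the one made with the preset correlation.

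The named genes are, for each drug contrast, members of a list that passed the gene test (at most 3 per list) and the 8 largest rises and 8 largest falls among passing genes with a mean log2 CPM of at least 5 and both drug libraries on the same side of both controls. Markers of other classes, haemoglobin, immunoglobulin and mitochondrial genes, and the X-linked transcripts Xist and Tsix, were left out of the largest changes. Where fewer than 5 genes passed, the 5 with the smallest p are named and stated as not passing. Tsc22d3, Ltf, Ncoa1, Ncoa2 and Ncoa3 are named in every class; Tsc22d3 and Ltf were known from the study, so they are not independent evidence. Ltf had too few counts to be tested in any of the 3 main classes. For the time contrast the 5 largest rises and falls and up to 2 members per list are eligible, and the text gives a selection of these. Up to 3 members of each passing list, those with the smallest p in the direction of the list, are given as examples; this was decided after values had been seen, and a selection is given.

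Shares of cells per class were compared with an exact permutation test over all 36 assignments of the libraries to the arms within each time, whose smallest possible p is 0.0556. Cell numbers per class were also tested in edgeR. Gene positions are those of GENCODE vM21 on GRCm38. DESeq2 1.42.0 served as the second test. Cell steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. In a self-test, counts were drawn from a negative binomial with the sizes and spreads of the real libraries, and 200 genes were changed by log2 1 or log2 2. At 24 h the pipeline recovered 34.7% and 84% of them in fibroblasts, 22.7% and 75.8% in macrophages, and 7.1% and 60.2% in endothelial cells. At 12 weeks it recovered 28.3% and 83.3%, 29.6% and 85.9%, and 31% and 88.8%. A list planted with a shift of log2 0.5 was called in 6 of 6 runs with the preset correlation and in 2 of 6, both in fibroblasts, with the estimated one. Of the unshifted lists 1 was also called, in fibroblasts at 24 h with the preset correlation. The self-test drew each gene independently of the others, so list members had no correlation. It therefore cannot show how often the preset correlation calls unshifted lists in real data. Of the genes called, those not changed were 15 of 133 in fibroblasts, 13 of 110 in macrophages and 4 of 70 in endothelial cells at 24 h, and 4 of 112, 14 of 128 and 9 of 127 at 12 weeks.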

Results

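Fibroblasts, the matrix-producing cells of the heart wall, and macrophages, the phagocytes that clear dead tissue, made up most of the captured cells at both times after infarction. At 24 h fibroblasts were 70.9 ± 0.363% (SD) of the cells of control hearts and 62.6 ± 2.56% with drug, and macrophages were 17.0 ± 0.975% and 24.0 ± 1.83%. At 12 weeks fibroblasts were 34.6 ± 4.98% in controls and 32.8 ± 6.96% with drug, and macrophages 35.5 ± 3.15% and 28.6 ± 2.44%. Blood endothelial cells, which line the vessels, were 1.93 ± 1.47% and 1.56 ± 0.196% at 24 h and 19.8 ± 7.74% and 24.3 ± 1.34% at 12 weeks. Granulocytes, the early inflammatory cells, were 0.988 ± 0.411% and 2.37 ± 0.993% at 24 h, and 0.0998 ± 0.0313% and 0.556 ± 0.679% at 12 weeks. Both drug hearts had a larger macrophage share than both controls at 24 h and a smaller one at 12 weeks, so the drug effect at 12 weeks minus that at 24 h was -14.0 percentage points (n = 2 hearts per group). No p is given for it, as it was looked at because the arms did not overlap. The 24 h difference of 7.07 points depends on how macrophages are defined. It was 2.61 points without the cluster with cardiomyocyte transcripts, an alternative chosen after seeing the data, and 3.51 points with classes from marker UMIs. At 12 weeks the difference was -6.94 points, and -7.06 and -2.98 points in these 2 alternatives. Over both times together the exact permutation p was 0.167 for fibroblasts, 0.944 for macrophages, 0.778 for endothelial cells and 0.167 for granulocytes. This test takes the mean of the differences at the 2 times. For macrophages that mean was 0.066 points, as the opposite differences cancel, so its p decides nothing about either time alone. Different clusters hold these classes at the 2 times: clusters 0, 2 and 3 hold the fibroblasts of 24 h and clusters 1, 13, 14 and 15 those of 12 weeks, and macrophages sit in clusters 7 and 12 at 24 h and in 10, 25 and 26 at 12 weeks. The lowest UMI count per cell was 3779 to 4976 in the 24 h libraries and 497 to 500 in the 12 week libraries, so shares are set against each other only within a time, and between the times only their drug effects are. Granulocytes were too few for a test of genes, with 12 and 33 cells in the 24 h controls and 8 to 116 in the 12 week libraries.

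**Figure D1:**
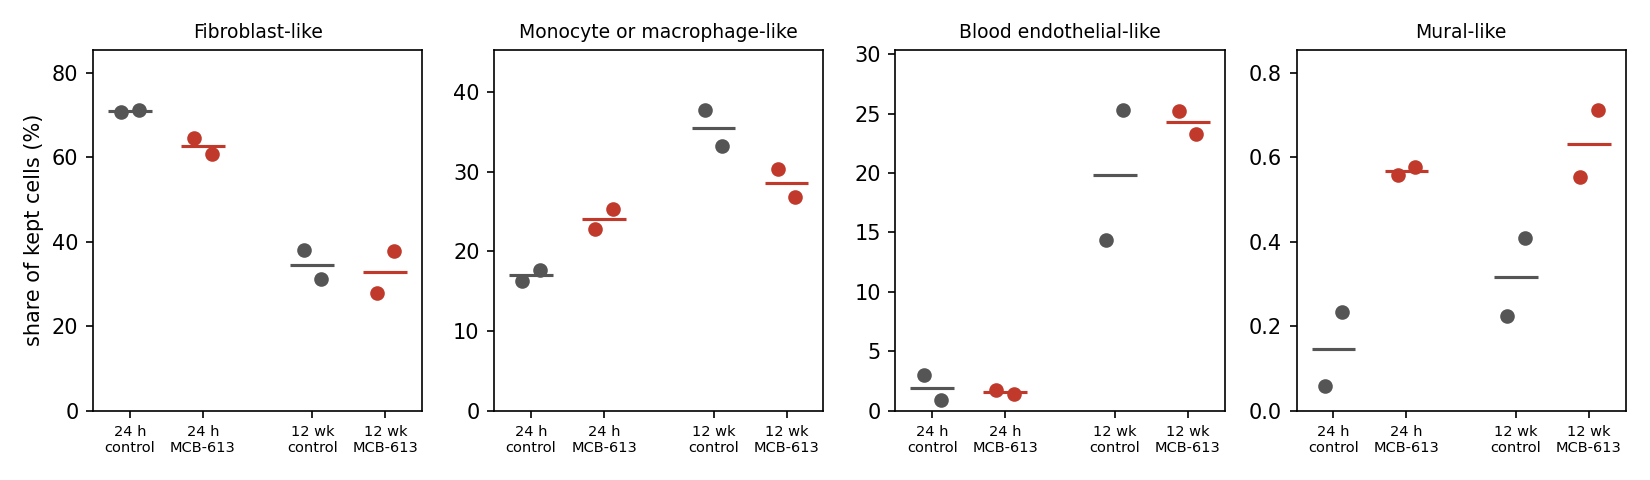
Share of cells per class in each of the 8 libraries. Macrophages were 17.0% of control and 24.0% of drug cells at 24 h, and 35.5% and 28.6% at 12 weeks.

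In fibroblasts at 24 h the drug hearts had lower levels of genes for cell division and glycolysis and higher levels of genes of quiescent fibroblasts, as lists and with the preset correlation only. With an estimated correlation the adjusted p was 0.355, 0.425 and 0.497, and no member passed over all genes. The mix of clusters moved too. Cluster 3 held 40.7% and 45.8% of the fibroblasts in controls and 52.7% and 63.4% with drug, and cluster 2 held 35.3% and 32.0% in controls and 29.3% and 16.8% with drug. In clusters 0, 2 and 3 fitted alone, a test chosen after seeing the data, the medians were -0.30, -0.21 and -0.35 for the cell cycle, -0.03, -0.41 and -0.04 for hypoxia and glycolysis and 0.04, 0.18 and 0.04 for quiescent fibroblast genes. The 1 gene that passed the test was Zfp979, a zinc finger gene on chromosome 4 (147611937 to 147642513). It had 0 counts in both controls and stood at 3.49 and 3.29 CPM with drug, from 164 UMIs (adjusted p = 0.0294, n = 2 hearts per group). The lactate exporter gene Slc16a3 stood at 197 and 179 CPM in controls and 67.3 and 81.7 CPM with drug (log2 change -1.34 ± 0.14, adjusted p = 0.0901). Lefty1, a secreted inhibitor of nodal signalling, stood at 0 and 0.921 CPM in controls and 13.4 and 16.3 CPM with drug (4.78 ± 0.57, adjusted p = 0.0941). At 12 weeks it stood at 47.9 and 49.1 CPM in controls and 52.4 and 60.4 CPM with drug, so it was near absent only in the 24 h controls.

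Among the fixed lists, 11 of 25 differed in fibroblasts at 24 h with the preset correlation, 6 higher and 5 lower. All 30 cell cycle genes had lower values with drug (median log2 change -0.68; adjusted p = 0.355 with an estimated correlation). When adjusted over the list alone 16 of them fell, though none passed over all genes; examples are the cyclin-dependent kinase partner Cks2 at -0.89 ± 0.16, the anaphase activator Cdc20 at -1.20 ± 0.23 and the mitotic kinase Plk1 at -1.56 ± 0.32. Hypoxia and glycolysis genes were lower in 24 of 25 (median -0.47; adjusted p = 0.425 with an estimated correlation), 7 of them passing when adjusted over the list alone. The glycolytic enzyme gene Pfkl stood at 101 and 86.7 CPM in controls and 47.4 and 46.5 CPM with drug, and Eno1 had a log2 change of -0.92 ± 0.21. Unfolded protein response genes were lower in 20 of 25 (median -0.22; adjusted p = 0.711 with an estimated correlation), with asparagine synthetase Asns at -0.85 ± 0.20 and the disulfide isomerase Pdia4 at -0.53 ± 0.20. Activated fibroblast or myofibroblast genes were lower in 20 of 31 (median -0.39; adjusted p = 0.711 with an estimated correlation). The matricellular genes Cyr61 (-0.93 ± 0.18) and Ctgf (-2.29 ± 0.69) are examples, and Cyr61 alone of this list fell when adjusted over the list alone. Dissociation-associated genes were lower in 20 of 28 (median -0.13; adjusted p = 0.752 with an estimated correlation), with the immediate early gene Ier3 at -0.77 ± 0.19. Without the first drug heart the median was 0.03.

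Quiescent fibroblast genes were higher in 19 of 24 (median 0.33; adjusted p = 0.497 with an estimated correlation), with the lipid transporter gene Abca8a at 0.62 ± 0.14 and apolipoprotein D, Apod, at 1.45 ± 0.33. When adjusted over the list alone 2 of them rose. Mitochondrially encoded genes were higher in 12 of 13 (median 0.24; adjusted p = 0.425 with an estimated correlation), with the complex I gene mt-Nd2 at 0.53 ± 0.12. Complement genes were higher in 14 of 18 (median 0.24; adjusted p = 0.607 with an estimated correlation), with C1qb at 1.44 ± 0.25; C1qa, C1qb and C1qc, which lead this list, are macrophage markers. Lists named for other cells were also higher in the drug fibroblasts. Not all of their members are foreign to fibroblasts: Saa3 is among the 10 top genes of fibroblast clusters 2 and 3, and Saa3 and Lcn2 are among those of a fibroblast cluster at resolution 0.5. Resident macrophage genes were higher in 17 of 22 (median 0.75; adjusted p = 0.425 with an estimated correlation), with the scavenger receptor Stab1 at 0.99 ± 0.21 and factor XIII, F13a1, at 0.94 ± 0.21. Inflammatory monocyte genes were higher in 15 of 18 (median 0.47; adjusted p = 0.425 with an estimated correlation), with the acute phase gene Saa3 at 1.38 ± 0.36. Neutrophil granule genes were higher in 16 of 17 (median 0.72; adjusted p = 0.711 with an estimated correlation), with lipocalin 2, Lcn2, at 1.21 ± 0.56. When adjusted over the list alone 2 resident macrophage genes, 1 mitochondrial and 1 complement gene rose, and no monocyte or neutrophil gene did. The share of RNA carried over from other cells was not measured. In the 4 fits that leave out 1 heart of 24 h, the calls for activated fibroblast, inflammatory monocyte and neutrophil genes held in 3, and those for mitochondrially encoded, complement and dissociation genes in 2. Without the second drug heart the median was 0.25 for neutrophil genes and 0.20 for monocyte genes, and without the second control heart it was -0.19 for activated fibroblast genes.

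Of the other genes fixed for every class, Tsc22d3, a glucocorticoid-induced leucine zipper gene, had a log2 change of 1.07 ± 0.73 in fibroblasts at 24 h (adjusted p = 0.573), and the coactivators Ncoa1, Ncoa2 and Ncoa3 had 0.43 ± 0.17, 0.24 ± 0.19 and -0.06 ± 0.25 (adjusted p = 0.337, 0.632 and 0.953). Nkain4, which encodes a partner of the sodium pump, stood at -3.05 ± 0.35 and the zinc finger gene Zfp984, next to Zfp979 on chromosome 4, at 3.08 ± 0.37 (adjusted p = 0.0941 for each). The lists of glucocorticoid receptor targets (median 0.35, adjusted p = 0.0894) and of steroid receptor coactivators and nuclear receptors (median 0.17, adjusted p = 0.39) did not pass. The gene test had 13375 genes, of which 1718 had an unadjusted p under 0.05 by edgeR, and DESeq2 called 177 genes, 64 higher and 113 lower. With only genes that have counts in every library, an alternative chosen after seeing the data, the count was 0.

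In fibroblasts at 12 weeks no single gene passed, and 3 of the 5 genes with the smallest p, Ciart, Arntl and Hlf, belong to the circadian clock or its output. Ciart, a repressor of the clock, stood at 2.54 and 1.68 CPM in controls and 19.7 and 13.9 CPM with drug (log2 change 2.99 ± 0.31, adjusted p = 0.166). Arntl, which encodes the clock activator BMAL1, stood at 25.6 and 29.9 CPM in controls and 2.70 and 5.80 CPM with drug (-2.67 ± 0.31, adjusted p = 0.166). The cell cycle kinase Wee1 (1.43 ± 0.21, adjusted p = 0.567), the clock-output factor Hlf (1.31 ± 0.20, adjusted p = 0.572) and Lingo1 (1.60 ± 0.28, adjusted p = 0.891) complete the 5. Passing genes numbered 0 of 13375 by edgeR, with 496 at an unadjusted p under 0.05 and 17 by DESeq2.

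At 12 weeks 6 of 25 lists differed in fibroblasts with the preset correlation, and no member passed when adjusted over the list alone. Activated fibroblast genes were higher in 26 of 31 (median 0.53; adjusted p = 0.662 with an estimated correlation), with the collagen-associated gene Cthrc1 at 1.15 ± 0.40 and the growth factor Tgfb3 at 0.35 ± 0.15; without the second drug heart the median was -0.04. Extracellular matrix genes were higher in 24 of 33 (median 0.28; adjusted p = 0.662 with an estimated correlation), with the matrix cross-linking enzyme Loxl2 at 0.62 ± 0.17 and the collagen-binding gene Sparc at 0.49 ± 0.15. Neutrophil granule genes were higher in 14 of 17 (median 1.03, or 0.96 with 18 counts for groups at 0; adjusted p = 0.662 with an estimated correlation). This rests on 1 drug heart, where the antimicrobial gene Camp stood at 23.5 CPM against 1.25 CPM in the other, and the calprotectin gene S100a9 at 45.0 against 1.17 CPM. Without it the median was -0.07. Unfolded protein response genes were lower in 22 of 25 (median -0.32; adjusted p = 0.662 with an estimated correlation), with Pdia4 at -0.63 ± 0.21 and the endoplasmic reticulum gene Sdf2l1 at -1.55 ± 0.51. Without the second control heart the median was 0.12. Dissociation-associated genes were lower in 26 of 28 (median -0.38; adjusted p = 0.726 with an estimated correlation), with the immediate early genes Egr2 at -0.54 ± 0.17 and Jund at -0.40 ± 0.15. Without the second control heart the median was 0.33. Cell cycle genes were lower in 21 of 30 (median -0.27; adjusted p = 0.662 with an estimated correlation), with the chromatin gene Hmgb2 at -0.37 ± 0.14. In the 4 fits that leave out 1 heart of 12 weeks, the calls for unfolded protein response, dissociation and cell cycle genes held with their direction in 3, and those for activated fibroblast, matrix and neutrophil genes in 2; the matrix median was 0.02 without the second drug heart. The cell cycle median turned to 0.06 without the first control heart, to 0.67 with doublets kept and to 0.06 with classes from marker UMIs. Tsc22d3 stood at 0.26 ± 0.72, Ncoa1 at -0.01 ± 0.17, Ncoa2 at 0.10 ± 0.20 and Ncoa3 at -0.34 ± 0.25, each with an adjusted p of 1.

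The drug effect on fibroblasts differed between the times in lists with the preset correlation, in 0 lists with an estimated one or with fry, and in 0 single genes by edgeR and 52 by DESeq2. Glycolysis and activated fibroblast genes had a higher effect at 12 weeks than at 24 h, and resident macrophage and quiescent fibroblast genes a lower one. At 12 weeks alone hypoxia and glycolysis genes did not pass in fibroblasts (median 0.09, adjusted p = 0.24 with the preset correlation). Their difference thus comes mainly from the lower values at 24 h (median -0.47). Between the times 6 of 25 lists differed with the preset correlation. The median difference was 0.66 for hypoxia and glycolysis (adjusted p = 0.504 with an estimated correlation), with 7 members passing when adjusted over the list alone, and 0.72 for activated fibroblast genes (adjusted p = 0.592 with an estimated correlation). It was 0.48 for the cell cycle and -0.39 for quiescent fibroblast genes (adjusted p = 0.695 with an estimated correlation for each). It was -1.14 for resident macrophage genes and -0.44 for mitochondrially encoded genes (adjusted p = 0.504 with an estimated correlation for each). The macrophage share of these hearts was 17.0% in controls and 24.0% with drug at 24 h, and 35.5% and 28.6% at 12 weeks. RNA carried over from macrophages was not measured, so the resident macrophage difference is not shown to arise in fibroblasts. Single genes passed in 0 of 13375 cases by edgeR, with 1060 at an unadjusted p under 0.05 and 52 by DESeq2. The smallest p belong to Zfp979 and Ciart (difference 4.37 ± 0.46 for Ciart; adjusted p = 0.0828 for each), Arntl (-3.72 ± 0.41, adjusted p = 0.0834), the amino acid transaminase Bcat1 (1.56 ± 0.20, adjusted p = 0.152) and the scaffold gene Sash1 (-1.57 ± 0.21, adjusted p = 0.212).

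In macrophages at 24 h the drug hearts had lower levels of genes of lipid-laden macrophages, of glycolysis and of cell division, and higher levels of genes of resident macrophages, as lists and with the preset correlation only. With an estimated correlation the adjusted p was 0.147 for lipid-handling genes and 0.449 for the other 3 lists, and no single gene passed. Spp1, which encodes osteopontin, stood at 6119 and 7296 CPM in controls and 2699 and 1668 CPM with drug (log2 change -1.62 ± 0.41, adjusted p = 0.518). Plin2, a coat protein of lipid droplets, stood at 1280 and 1100 CPM in controls and 506 and 364 CPM with drug (-1.45 ± 0.29, adjusted p = 0.276). Igf1, a growth factor made by resident macrophages, stood at 51.9 and 59.5 CPM in controls and 90.6 and 126 CPM with drug (0.96 ± 0.21, adjusted p = 0.416). The mix of clusters moved in the same direction. Cluster 7, whose top genes are Arg1 and Spp1, held 72.9% and 62.5% of the macrophages in controls and 54.2% and 49.8% with drug. Cluster 12, with C1qb and F13a1 and with cardiomyocyte transcripts, held 24.3% and 34.0% in controls and 40.2% and 46.1% with drug. In clusters 7 and 12 fitted alone, a test chosen after seeing the data, the medians were -0.55 and -0.11 for lipid-handling genes, -0.13 and -0.25 for hypoxia and glycolysis, -0.57 and -0.59 for the cell cycle and 0.18 and 0.22 for resident macrophage genes. No gene passed alone: the count was 0 of 11990 by edgeR, with 863 at an unadjusted p under 0.05, and 29 by DESeq2, 15 higher and 14 lower.

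As lists, 13 of 25 differed in macrophages at 24 h with the preset correlation, 5 higher and 8 lower. Lipid-handling genes of the Trem2 type were lower in 15 of 19 (median -0.47; adjusted p = 0.147 with an estimated correlation), and this was the 1 list that fry also called (adjusted p = 0.0313). When adjusted over the list alone 7 of its members fell and 2 rose; the cathepsin gene Ctsl stood at -0.98 ± 0.26. Cell cycle genes were lower in 30 of 30 (median -0.58; adjusted p = 0.449 with an estimated correlation), with the survivin gene Birc5 at -1.40 ± 0.49 and the tubulin gene Tubb5 at -0.41 ± 0.18. Hypoxia and glycolysis genes were lower in 24 of 26 (median -0.41; adjusted p = 0.449 with an estimated correlation), with Eno1 at -0.87 ± 0.23 and the pyruvate kinase gene Pkm at -0.60 ± 0.23. Unfolded protein response genes were lower in 21 of 24 (median -0.26; adjusted p = 0.449 with an estimated correlation), 2 of them passing when adjusted over the list alone, with the chaperone Hspa5 at -0.92 ± 0.25 and Pdia4 at -0.78 ± 0.18. Matrix proteases and inhibitors were lower in 12 of 18 (median -0.33), with the membrane-bound protease Mmp14 at -1.49 ± 0.30 and the urokinase receptor Plaur at -0.60 ± 0.21. Angiogenesis genes (median -0.28), activated fibroblast genes (-0.30) and TGF-beta and SMAD targets (-0.17) were lower as well. The median of activated fibroblast genes turned to 0.21 with doublets kept, and that of TGF-beta targets to 0.05 without cluster 12. For these 4 lists the adjusted p was 0.449 with an estimated correlation, and when adjusted over the list alone 1 protease gene rose and 1 fell. In the 4 fits that leave out 1 heart of 24 h, the calls for cell cycle and angiogenesis genes held in 3, those for proteases and activated fibroblast genes in 2 and that for TGF-beta targets in 0. Without the first control heart the median was -0.17 for the cell cycle, -0.22 for hypoxia and glycolysis, -0.04 for angiogenesis and -0.03 for proteases.

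Resident and reparative macrophage genes were higher in 19 of 23 at 24 h (median 0.54; adjusted p = 0.449 with an estimated correlation), with the scavenger receptor Stab1 at 0.64 ± 0.20, and 1 of them rose when adjusted over the list alone. Mitochondrially encoded genes were higher in 12 of 13 (median 0.46; adjusted p = 0.449 with an estimated correlation), 2 of them passing when adjusted over the list alone, with the complex I gene mt-Nd3 at 1.02 ± 0.20. Nuclear genes of oxidative phosphorylation were higher in 29 of 36 (median 0.17; adjusted p = 0.783 with an estimated correlation). Cardiomyocyte RNA was higher in 10 of 15 genes (median 0.19, and -0.09 with classes from marker UMIs), with the calcium pump regulator Pln at 0.80 ± 0.32, and neutrophil granule genes in 11 of 16 (median 0.46), with the oxidase gene Cybb, which macrophages also express, at 0.48 ± 0.18 (adjusted p = 0.686 with an estimated correlation for both lists). Without 1 heart the neutrophil call held in 3 of 4 fits, with a median of 0.10 without the second drug heart, and those for cardiomyocyte RNA and oxidative phosphorylation in 2. The 5 genes with the smallest p, each with an adjusted p of 0.275, are Gm20703, Rd3 and Asgr2, which had 0 counts in both controls and 62, 48 and 35 UMIs with drug, Zfp984 (2.76 ± 0.46) and the GTPase-activating protein gene Arhgap19 (1.40 ± 0.24). For the first 3, 9 cells per control library at 1 UMI per cell would be 2.53 CPM, against 4.08, 3.16 and 2.30 CPM with drug. The 24 h controls hold fewer cells (1719 and 2581) than the drug hearts (4127 and 3804). They also have more genes at 0 (2791 and 2215 against 1731 and 1733). Tsc22d3 stood at 0.84 ± 0.35 (adjusted p = 0.686), and Ncoa1, Ncoa2 and Ncoa3 at 0.27 ± 0.41, 0.50 ± 0.28 and -0.07 ± 0.30 (adjusted p = 0.918, 0.732 and 0.98). The list of coactivators and nuclear receptors had a median of 0.07 (adjusted p = 0.724).

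In macrophages at 12 weeks genes of the cell cycle and of glycolysis had higher values with drug, as lists and with the preset correlation only. Mcm3 and Mcm5, subunits of the replication helicase, had log2 changes of 1.02 ± 0.24 and 1.34 ± 0.35 (adjusted p = 1 for each). Of the cell cycle genes 28 of 30 were higher (median 0.43; adjusted p = 0.987 with an estimated correlation), and 4 rose when adjusted over the list alone. So were hypoxia and glycolysis genes in 22 of 26 (median 0.29), with Gapdh at 0.63 ± 0.24 and the hexokinase gene Hk1 at 0.44 ± 0.22. Matrix proteases and inhibitors were higher in 10 of 18 (median 0.12), with the macrophage elastase Mmp12 at 1.51 ± 0.40, and 3 members rose when adjusted over the list alone. Glucocorticoid receptor targets were higher in 13 of 18 (median 0.19), with the clock gene Per1 at 0.72 ± 0.26 and the mTOR inhibitor Ddit4 at 0.89 ± 0.27. For these 3 lists the adjusted p was 0.987 with an estimated correlation. Neutrophil granule genes were higher in 12 of 16 (median 1.69, or 0.71 with 18 counts for groups at 0; adjusted p = 0.987 with an estimated correlation), with Prtn3 at 21.9 CPM in 1 drug heart and 2.36 CPM in the other; without the first the median was -0.23. In the 4 fits that leave out 1 heart of 12 weeks, the calls for cell cycle, protease and neutrophil genes held in 3, and those for hypoxia and glycolysis and for glucocorticoid receptor targets in 2. The median was 0.05 for the cell cycle without the second drug heart, 0.07 for hypoxia and glycolysis without the first, and 0.01 for glucocorticoid receptor targets without the first control heart.

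No single gene passed in macrophages at 12 weeks: the count was 0 of 11990 by edgeR, with 362 at an unadjusted p under 0.05, and 1 by DESeq2. The smallest p belong to Dgat2, an enzyme of triglyceride synthesis (1.87 ± 0.33), the cathepsin gene Ctsk (2.27 ± 0.41), Gm48065 (0 counts in both controls and 22 UMIs with drug) and the immediate early gene Egr2 (-0.94 ± 0.17), each with an adjusted p of 0.75, and to the DNA methylation partner Uhrf1 (1.40 ± 0.28, adjusted p = 1). Tsc22d3 stood at 0.15 ± 0.35, Ncoa1 at -0.04 ± 0.37, Ncoa2 at -0.23 ± 0.23 and Ncoa3 at -0.45 ± 0.29 (adjusted p = 1 for each). Without 1 drug heart at 12 weeks 33 genes passed.

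Between the times the drug effect on macrophages differed in lists with the preset correlation, among them the cell cycle, glycolysis and resident macrophage genes. With an estimated correlation or with fry 0 lists passed. The median difference, 12 weeks minus 24 h, was 1.15 for the cell cycle with 29 of 30 members higher, and 0.69 for hypoxia and glycolysis with 24 of 26 higher. It was -0.58 for mitochondrially encoded genes, -0.56 for resident macrophage genes and 0.61 for matrix proteases and inhibitors. For these 5 lists the adjusted p was 0.408 with an estimated correlation, and 3, 0, 2, 1 and 5 members passed when adjusted over the list alone. Lipid-handling genes had a median of 0.45 (adjusted p = 0.339 with an estimated correlation), angiogenesis genes 0.63 (adjusted p = 0.569 with an estimated correlation), unfolded protein response genes 0.21 (adjusted p = 0.671 with an estimated correlation) and cardiomyocyte RNA -0.11 (adjusted p = 0.835 with an estimated correlation), which makes 9 of 25 lists; when adjusted over the list alone 3 lipid-handling genes were higher and 1 lower. Single genes passed in 0 of 11990 cases by edgeR, with 821 at an unadjusted p under 0.05 and 20 by DESeq2. The smallest p, with an adjusted p of 0.298, belong to Egr2 (-1.45 ± 0.26) and to Gm20703, Gm454, Lbx1 and 5033421B08Rik, which had 0 counts in both 24 h controls. There a 0 can stand for up to 9 cells per library.

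In endothelial cells at 24 h the drug hearts had less of the monocyte attractant Ccl2 and more of Car4 and Sparcl1. Glycolytic genes were lower as a list, with the preset correlation only (adjusted p = 0.451 with an estimated correlation). Ccl2 fell from 649 and 876 CPM in controls to 74.6 and 52.4 CPM with drug (log2 change -3.55 ± 0.37, adjusted p = 0.00374). The enolase gene Eno1 fell (-1.35 ± 0.24, adjusted p = 0.0324), as did Uap1, an enzyme of hexosamine synthesis (-1.77 ± 0.30, adjusted p = 0.0236). Car4, a carbonic anhydrase of capillary endothelium, rose from 53.6 and 35.8 CPM to 228 and 219 CPM (2.28 ± 0.37, adjusted p = 0.0236), and Sparcl1, a matricellular gene, from 124 and 76.0 CPM to 386 and 447 CPM (2.02 ± 0.31, adjusted p = 0.0146). The cell cycle regulator Rgcc (2.03 ± 0.33, adjusted p = 0.0241), the surface antigen Ly6c1 (1.70 ± 0.31, adjusted p = 0.0369), the secreted factor C1qtnf9 (2.76 ± 0.41, adjusted p = 0.0118) and the linker histone gene Hist1h1c (2.73 ± 0.50, adjusted p = 0.0369) rose as well.

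**Figure D2:**
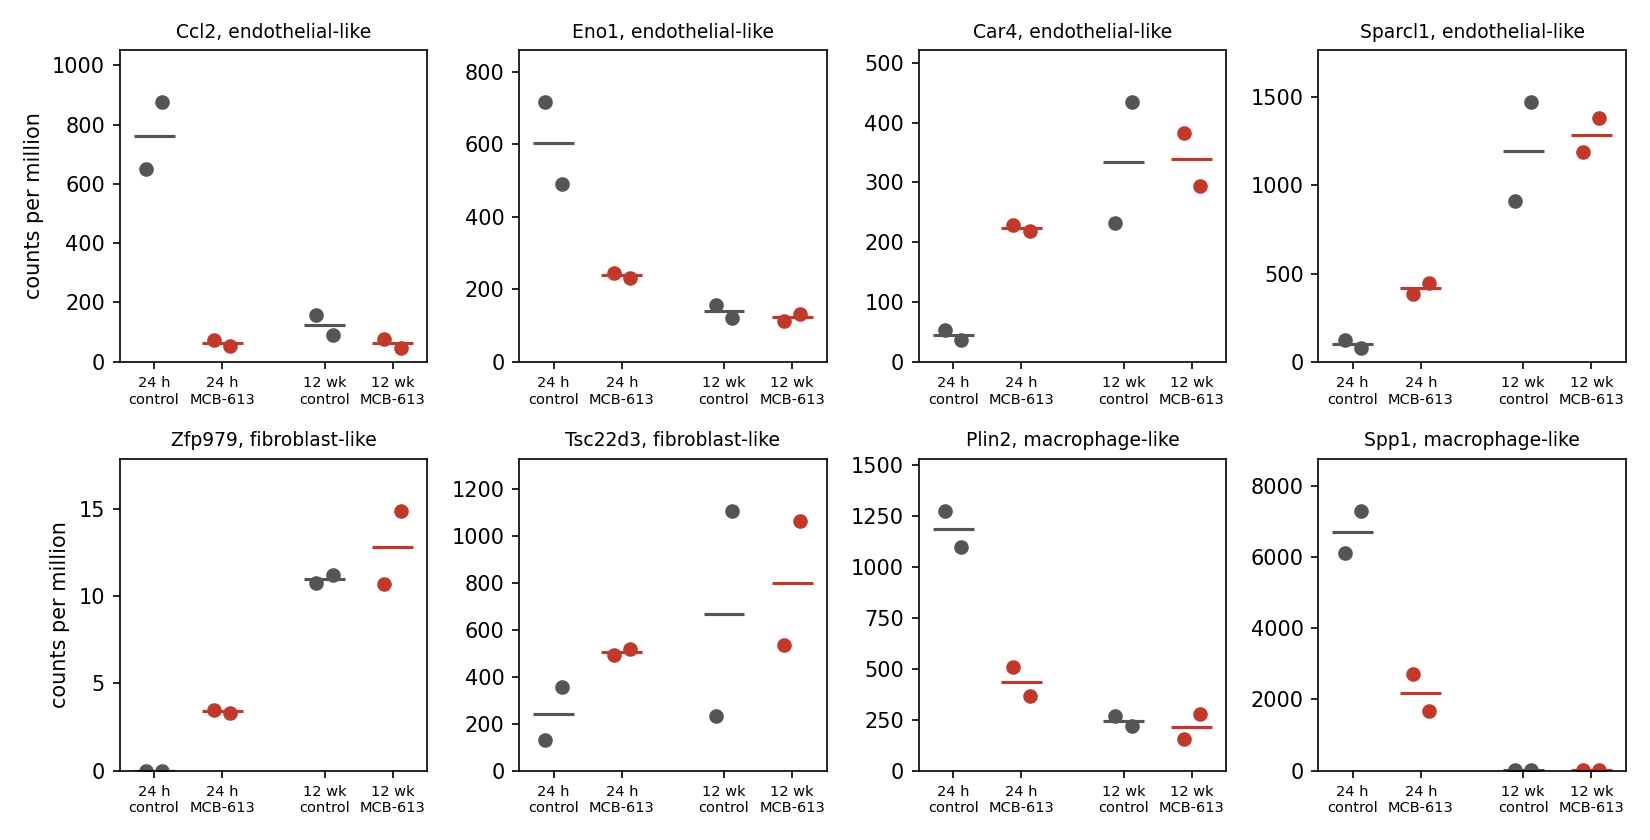
CPM of 8 genes in each library, dots for libraries and bars for group means. In endothelial cells at 24 h Ccl2 stood at 649 and 876 CPM in controls and 74.6 and 52.4 CPM with drug.

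Zfp979 and the antisense transcript Gm12002 had 0 counts in the endothelial cells of both 24 h controls and 24 and 33 UMIs with drug (adjusted p = 0.0236 and 0.0118). A 0 can stand for up to 9 cells in each library, which at 1 UMI per cell would be 30.2 CPM in these controls against 29.2 and 40.2 CPM with drug. In all 13 of 9209 genes passed, 10 higher and 3 lower. DESeq2 called 64 genes, 35 higher and 29 lower. The controls hold only 51 and 23 endothelial cells and the drug hearts 70 and 54, and without 1 control heart the count was 1 or 20. Classes from marker UMIs per cell leave 20 and 8 endothelial cells in the 24 h controls, too few for a test. In cluster 19 fitted alone, a test chosen after seeing the data, 3 genes passed, 1 higher and 2 lower. In the 24 h hearts 72.9% to 95.7% of these cells belong to cluster 19, while cluster 24 holds 11.8% and 0% of them in the controls and 25.7% and 18.5% with drug. For the genes named above that rose, this change of mix cannot be told apart from a change within cells. Cluster 19 still held 72.9% and 79.6% of these cells with drug. That argues against the mix as the whole cause for Ccl2, Uap1 and Eno1, which fell by more than this share did. In cluster 19 alone the list medians were -0.68 for hypoxia and glycolysis and -0.47 for the unfolded protein response, close to those of the class.

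As lists, 8 of 25 differed in endothelial cells at 24 h with the preset correlation. Genes of hypoxia and glycolysis were lower in 18 of 24 (median -0.68; adjusted p = 0.451 with an estimated correlation). When adjusted over the list alone 11 fell and 1 rose, against Eno1 alone over all genes; the phosphoglycerate kinase gene Pgk1 stood at -1.03 ± 0.21 and Pkm at -1.06 ± 0.22. Unfolded protein response genes were lower in 18 of 24 (median -0.47; adjusted p = 0.451 with an estimated correlation), with the disulfide isomerases Pdia6 at -1.07 ± 0.23 and Pdia3 at -0.94 ± 0.22, and 7 fell when adjusted over the list alone. Inflammatory cytokines and chemokines were lower in 16 of 19 (median -0.45; adjusted p = 0.451 with an estimated correlation), where Ccl2 was the 1 gene that passed. Cell cycle genes were lower in 11 of 13 (median -0.52; adjusted p = 0.451 with an estimated correlation), with Tubb5 at -0.65 ± 0.22, and activated fibroblast genes in 12 of 20 (median -0.33; adjusted p = 0.451 with an estimated correlation). Glucocorticoid receptor targets were higher in 15 of 16 (median 0.73; adjusted p = 0.451 with an estimated correlation), with Ddit4 at 0.87 ± 0.32. Mitochondrially encoded genes were higher in 10 of 13 (median 0.41; adjusted p = 0.669 with an estimated correlation), with mt-Nd2 at 0.79 ± 0.25. Cardiomyocyte RNA was higher in 4 of 5 genes (median 2.03; adjusted p = 0.681 with an estimated correlation), with the troponin gene Tnni3 at 2.82 and 0 CPM in controls and 15.4 and 30.8 CPM with drug, and 1 gene rose when adjusted over the list alone. In the 4 fits that leave out 1 heart of 24 h, the calls for cell cycle, activated fibroblast and mitochondrially encoded genes held in 2 and that for cardiomyocyte RNA in 1. Without the first control heart the median was -0.04 for activated fibroblast genes and -0.01 for cytokines. Tsc22d3 stood at 1.01 ± 0.38 (adjusted p = 0.399), and Ncoa1, Ncoa2 and Ncoa3 at 0.92 ± 0.76, 0.59 ± 0.86 and 0.16 ± 0.37 (adjusted p = 0.75, 0.879 and 0.939).

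In endothelial cells at 12 weeks no gene passed, and 3 of the 5 genes with the smallest p, Tef, Dbp and Arntl, belong to the circadian clock or its output. The clock-output factors Tef and Dbp had log2 changes of 1.04 ± 0.21 and 1.16 ± 0.27 and the clock activator Arntl -2.19 ± 0.58, with Fam124b at -2.10 ± 0.51 and the membrane protein gene Mal at 1.02 ± 0.27 (adjusted p = 1 for each). Passing genes numbered 0 of 9209 by edgeR, with 123 at an unadjusted p under 0.05 and 0 by DESeq2. Of the lists 6 of 25 differed with the preset correlation, and no member passed when adjusted over the list alone. Unfolded protein response genes were lower in 18 of 24 (median -0.21), with Pdia6 at -0.54 ± 0.22 and a median of 0.01 without the second control heart, and glucocorticoid receptor targets were higher in 12 of 16 (median 0.30), with Ddit4 at 0.66 ± 0.24 and Per1 at 0.87 ± 0.33. Inflammatory cytokines and chemokines were lower, with a mean of -0.30, a median of -0.04 and Ccl2 at -0.97 ± 0.30. Cardiomyocyte RNA was lower in 5 of 5 genes (median -0.65), and granulocyte RNA higher in 4 of 5 (median 1.18), with the calprotectin gene S100a8 at 107 CPM in 1 drug heart and 3.41 CPM in the other; without the first the median was -0.14. For these 5 lists the adjusted p was 0.9 with an estimated correlation. Interferon-stimulated genes were lower in 15 of 24 (median -0.11; adjusted p = 0.901 with an estimated correlation). Without 1 heart of 12 weeks their call held in 1 of 4 fits, and those for unfolded protein response, glucocorticoid, cytokine and granulocyte genes in 2; glucocorticoid targets had a median of 0.03 without the first control heart. Tsc22d3 stood at 0.34 ± 0.33, Ncoa1 at 0.55 ± 0.41, Ncoa2 at 0.05 ± 0.37 and Ncoa3 at -0.18 ± 0.20 (adjusted p = 1 for each).

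Between the times the drug effect on endothelial cells differed in lists with the preset correlation, among them glycolysis, unfolded protein response and glucocorticoid target genes. With an estimated correlation or with fry 0 lists passed. The median difference, 12 weeks minus 24 h, was 0.66 for hypoxia and glycolysis, with 6 members passing when adjusted over the list alone, 0.58 for the cell cycle, -2.67 for cardiomyocyte RNA and 0.44, or 0.47 with 18 counts for groups at 0, for inflammatory cytokines (adjusted p = 0.707 with an estimated correlation for these 4 lists). It was 0.30 for unfolded protein response genes, -0.44 for mitochondrially encoded genes and -0.51 for glucocorticoid receptor targets (adjusted p = 0.76 with an estimated correlation for these 3), and 0.51 for activated fibroblast genes (adjusted p = 0.477 with an estimated correlation). Single genes passed in 0 of 9209 cases by edgeR, with 547 at an unadjusted p under 0.05 and 15 by DESeq2. The smallest p belong to Gm12002 and Zfp979 (adjusted p = 0.0838 for each), C1qtnf9 (-2.66 ± 0.48, adjusted p = 0.113), Ccl2 (2.59 ± 0.48) and Car4 (-2.26 ± 0.46; adjusted p = 0.294 for both). The median of inflammatory cytokines turned to -0.06 without the first 24 h control heart. At 12 weeks alone hypoxia and glycolysis genes did not pass in endothelial cells (median -0.03, adjusted p = 0.629 with the preset correlation).

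In control fibroblasts genes of cell division, inflammation and glycolysis were lower at 12 weeks than at 24 h. The chemokine genes Cxcl3 and Cxcl5 fell (log2 changes -8.46 ± 0.47 and -5.74 ± 0.24), as did the cytokine Il11 (-6.74 ± 0.38), the matrix gene Tnc (-6.24 ± 0.45) and the metalloproteinase inhibitor Timp1 (-5.65 ± 0.63). All 30 cell cycle genes fell (median -3.18; adjusted p = 0.17 with an estimated correlation), among them Cks2 at -3.62 ± 0.18 and Mcm5 at -4.40 ± 0.24. Hypoxia and glycolysis genes were lower (median -1.56), 17 of 25 passing over all genes and 18 when adjusted over the list alone, with Pgk1 at -2.62 ± 0.13 and Mif at -2.70 ± 0.15, as were inflammatory monocyte genes (median -2.15), with Saa3 at -5.57 ± 0.44 (adjusted p = 0.17 with an estimated correlation for both). Inflammatory cytokines (median -1.41) and matrix proteases (-0.68) were lower and resident macrophage genes higher (2.07; adjusted p = 0.309 with an estimated correlation for these 3). The extracellular protein gene Itih5 rose (4.04 ± 0.39), as did Cst6 (3.91 ± 0.86), Abca8a (1.89 ± 0.14), the glucocorticoid receptor gene Nr3c1 (1.44 ± 0.16) and C1qb (2.58 ± 0.26). C1qb is a macrophage marker, and RNA carried over from macrophages was not measured. The ribosomal protein genes Rpl10, Rpl21 and Rps18 rose by 4.58 ± 0.31, 3.97 ± 0.26 and 3.80 ± 0.17, which makes them 3 of the 5 largest rises. Whether the 2 times were processed with the same reference and cell calling is not given in the sources used here. The times were not separated from a difference there. It could raise these genes with no change in the cells and touch the time contrast of every class. In all 6025 of 13375 genes passed, 2914 higher and 3111 lower, and the 24 h libraries hold only cells of at least 3779 UMIs against 497 at 12 weeks.

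In control macrophages genes of inflammation and glycolysis were lower at 12 weeks than at 24 h, and genes of resident macrophages were higher. Spp1 fell (log2 change -10.16 ± 0.60), as did the arginase gene Arg1 (-8.81 ± 1.19), the chitinase-like gene Chil3 (-7.93 ± 0.96), Cxcl3 (-7.68 ± 0.76) and the ribonuclease gene Rnase2a (-7.08 ± 1.61). The lectin gene Cd209b had 0 counts at 24 h and 2239 UMIs at 12 weeks, and Cd209d (5.94 ± 0.69), Retnla (6.84 ± 1.58), the phospholipase Pla2g2d (5.32 ± 0.41) and Rpl10 (5.15 ± 0.32) rose. Resident macrophage genes were higher in 20 of 23 (median 1.53; adjusted p = 0.244 with an estimated correlation), with Timd4, a receptor for dying cells, at 3.10 ± 0.28 and Igf1 at 3.18 ± 0.23. Hypoxia and glycolysis genes were lower in 25 of 26 (median -2.80), 23 of them passing over all genes and 23 when adjusted over the list alone, among them Pgk1 (-3.77 ± 0.23) and Pkm (-3.59 ± 0.25). Inflammatory monocyte genes were lower in 18 of 18 (median -4.02), with Clec4e at -4.18 ± 0.31 and S100a4 at -3.74 ± 0.29, and matrix proteases in 14 of 18 (median -2.12), with Plaur at -3.42 ± 0.23. For these 3 lists the adjusted p was 0.103 with an estimated correlation. Lists of other cells were lower too with the preset correlation, with medians of -3.32 for granulocyte RNA and -1.255 for cardiomyocyte RNA. Extracellular matrix genes had -1.68 and quiescent fibroblast genes -1.087. RNA carried over from other cells was not measured. The complement gene C4b (2.64 ± 0.31) rose, while complement as a list did not pass (median -0.29, adjusted p = 0.254). In all 4871 of 11990 genes passed, 2585 higher and 2286 lower, and 20 of 25 lists, 4 higher and 16 lower.

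In control endothelial cells inflammatory cytokines (median -1.12), matrix proteases and inhibitors (-2.45) and genes of glycolysis were lower at 12 weeks than at 24 h (adjusted p = 0.159 and 0.181 with an estimated correlation for the first 2 lists). Selp, which encodes the leukocyte receptor P-selectin, fell (log2 change -5.63 ± 0.84), as did the protease gene Adamts4 (-6.71 ± 0.88), Timp1 (-6.21 ± 1.03) and the metallothionein gene Mt2 (-5.38 ± 0.41). The flow-responsive factor Klf2 rose (1.91 ± 0.24), as did Ncoa3 (2.23 ± 0.29), and the diaphragm gene Plvap fell (-2.79 ± 0.32). Gm12002, Zfp979, Ptprr, Ces2e and Pcdh17 had 0 counts in both 24 h controls and 840, 702, 333, 322 and 280 UMIs in the 12 week controls. Extracellular matrix genes were lower in 23 of 26, 12 of them passing over all genes and 14 when adjusted over the list alone (median -1.60; adjusted p = 0.159 with an estimated correlation), with the proteoglycan genes Dcn at -2.68 ± 0.25 and Bgn at -2.39 ± 0.29, which are markers of fibroblasts. Of the hypoxia and glycolysis genes 16 of 24 were lower (median -1.04; adjusted p = 0.258 with an estimated correlation), with Pgk1 at -2.69 ± 0.21 and Tpi1 at -2.32 ± 0.22. Unfolded protein response genes were lower in 20 of 24 (median -0.94; adjusted p = 0.252 with an estimated correlation). Interferon-stimulated genes were higher in 19 of 24 (median 0.45; adjusted p = 0.595 with an estimated correlation), with Xaf1 at 2.18 ± 0.31 and Slfn5 at 1.56 ± 0.25. Lists of other cells were lower too with the preset correlation, with medians of -3.19 for granulocyte RNA and -3.12 for inflammatory monocyte genes. Quiescent fibroblast genes had -2.335 and activated fibroblast genes -1.67. RNA carried over from other cells was not measured. In all 1730 of 9209 genes passed, 844 higher and 886 lower, and 12 of 25 lists, 1 higher and 11 lower.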

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

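All tests weighed in this part were chosen only after the result was seen, and so were the fits of each cluster alone and of 24 h cells with at least 5000 UMIs; the interaction contrast and the lists were planned. The drug effects of the 2 times differed for 23 lists over the 3 classes in the interaction contrast with the preset correlation, and for none with an estimated correlation. In fibroblasts the median difference, 12 weeks minus 24 h, was 0.66 for hypoxia and glycolysis, 0.722 for activated fibroblast genes, -1.139 for resident macrophage genes, 0.479 for the cell cycle, -0.444 for mitochondrially encoded genes and -0.388 for quiescent fibroblast genes. In macrophages it was 1.154 for the cell cycle, 0.694 for hypoxia and glycolysis, -0.584 for mitochondrially encoded genes, -0.561 for resident macrophage genes, 0.446 for lipid-handling genes, 0.607 for matrix proteases, 0.628 for angiogenesis, 0.213 for the unfolded protein response and -0.113 for cardiomyocyte RNA. In endothelial cells it was 0.658 for hypoxia and glycolysis, -2.674 for cardiomyocyte RNA, 0.509 for activated fibroblast genes, 0.296 for the unfolded protein response, -0.441 for mitochondrially encoded genes, 0.584 for the cell cycle, -0.51 for glucocorticoid receptor targets and 0.442 for inflammatory cytokines.

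The pattern weighed here is that genes of protein folding, glycolysis and cell division were lower with drug at 24 h in all 3 classes. A shift in the clusters within a class is argued against as the whole cause for the unfolded protein response and the cell cycle. Their medians were each below -0.1 in 8 of 8 clusters tested alone. Of these, cluster 5 (unnamed) and cluster 6 (dendritic) lie outside the 3 classes, and all come from the same hearts. For the cell cycle the fibroblast clusters had -0.305, -0.208 and -0.346 against -0.68 in the class. A shift fits for hypoxia and glycolysis in fibroblasts, whose median was below that limit in only 1 of 3 clusters. A higher UMI minimum in some 24 h libraries is argued against, since with cells of at least 5000 UMIs 9 of 9 medians, of the 3 lists in the 3 classes, kept most of their size; the smallest ratio to the median before was 0.874, for the unfolded protein response in fibroblasts. More handling stress in controls cannot be told apart, because the parts of the dissociation list differ. In fibroblasts the median of the list was below -0.1 in 3 of 3 clusters (-0.454, -0.205 and -0.326). Its heat shock members had -0.482 and its immediate early members -0.081 in the class. In macrophages and endothelial cells the whole list had 0.232 and 0.276. Its heat shock members had -0.26 and -0.527 there, and its immediate early members 0.284 and 0.329. An effect of the drug on cells in the first day remains possible, and the design, with 2 hearts per arm, gives no further test of it.

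The macrophage share was flagged because both drug hearts lay above both controls at 24 h (7.07 percentage points) and below both at 12 weeks (-6.94 points); since it was chosen for this, a permutation of the difference would decide nothing. Without the cluster with cardiomyocyte transcripts the 24 h difference was 2.61 points, and with classes from marker UMIs the differences were 3.51 and -2.98 points. Ltf, which encodes lactoferrin, was outside the 3 main classes and stood at 171 CPM over all cells of 1 drug heart at 12 weeks, above every control; that heart holds 116 granulocytes against 8 to 14 in the other 12 week hearts, and in it Ngp stood at 842, Camp at 601 and S100a8 at 2244 CPM.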

How the results depend on the processing

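The alternatives chosen only after the data were seen are genes with counts in every library, 24 h cells with at least 5000 UMIs, macrophages without the cluster with cardiomyocyte transcripts, crossed pairing at 12 weeks and each cluster alone. RLE size factors, stricter cells (500 genes, 10% mitochondrial UMIs) and 24 h cells with at least 5000 UMIs moved no gene count by more than 1.5 times. Over all settings other than leaving out a heart, 91 of 116 gene counts, 77 of 103 list counts and 68 of 76 shares kept their value within the limit set, and 1783 of 1880 values of single genes and 435 of 635 of single lists kept their direction and side of the threshold. Of the shares that kept their value, 4 are those with a replicate block, which leaves the difference unchanged by its construction. With 2 hearts per group, depth limits the endothelial cells of 24 h most among the 3 main classes. Their 2 control libraries hold 51 and 23 cells. The granulocyte contrasts were not run for want of cells, and an alternative that could not give a value has none here. Where no cause is named below, the cause was not tested. In a fit that leaves out a heart, the lone heart is assumed to vary like the other groups.

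With an estimated correlation 0 lists passed in all 12 comparisons. With fry 0 passed in 8 of the 9 drug comparisons and 1 in macrophages at 24 h. For time fry called 12 lists in fibroblasts, 19 in macrophages and 10 in endothelial cells. DESeq2 called 177 genes in fibroblasts at 24 h, 17 at 12 weeks and 52 for the difference between times, 29, 1 and 20 in macrophages, and 64 and 15 in endothelial cells at 24 h and for the difference. Without the filter on low counts, which tests more genes, endothelial counts were 126 at 24 h, 12 at 12 weeks and 42 for the difference. With only genes that have counts in every library 0 fibroblast genes passed at 24 h, since Zfp979 is then not tested. With only the 4 libraries of the time, which leaves fewer hearts to estimate the spread, the counts at 24 h were 0 in fibroblasts, 14 in macrophages and 22 in endothelial cells, and the median of inflammatory cytokines in endothelial cells at 12 weeks turned to 0.009. With doublets kept, 7 endothelial genes passed at 24 h, 8 macrophage lists passed at 24 h and 8 at 12 weeks, and medians turned to 0.669 for the cell cycle in fibroblasts at 12 weeks and 0.207 for activated fibroblast genes in macrophages at 24 h; Ncoa2 in endothelial cells at 12 weeks turned to -0.0314. With stricter cells 1 endothelial list passed at 12 weeks. Without the cluster with cardiomyocyte transcripts the median of TGF-beta and SMAD targets in macrophages at 24 h turned to 0.053, and shares at 24 h, drug minus control, moved to 2.61 points for macrophages and -4.71 points for fibroblasts, and to -2.22 points for macrophages over both times. With 24 h cells of at least 5000 UMIs Ncoa3 in endothelial cells at 24 h turned to -0.367.

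With classes from marker UMIs per cell, gene counts were 0 at 24 h, 1 at 12 weeks, 1 for the difference and 2716 for time in fibroblasts, and 8 macrophage lists passed at 24 h. Medians turned to 0.062 for the cell cycle in fibroblasts at 12 weeks, to -0.085 for cardiomyocyte RNA in macrophages at 24 h, and to 0.059 for inflammatory cytokines in endothelial cells at 12 weeks. Endothelial contrasts that use the 24 h hearts have no value here, since the controls then hold 20 and 8 cells. Ncoa2 in fibroblasts at 12 weeks turned to -0.0218 and Ncoa1 in macrophages at 12 weeks to 0.0081. Shares, drug minus control, moved to -4.51 points for fibroblasts at 24 h, 3.51 and -2.98 for macrophages at the 2 times, and 5.65 at 24 h and 3.19 over both times for granulocytes.

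The labels state no pairing of hearts, and the libraries share only a number. Residuals of libraries of the same number had correlations of -0.019 and -0.175 in fibroblasts at 24 h and 12 weeks, 0.031 and -0.044 in macrophages and 0.026 and -0.046 in endothelial cells, so the numbers are not shown to pair. A replicate block within time gave 0 fibroblast genes at 24 h, 1 macrophage gene at 24 h and 2 for the difference, 37 endothelial genes at 24 h and 8 for the difference, and 11 fibroblast lists at 12 weeks; Ncoa1 in fibroblasts at 12 weeks turned to 0.0035. Crossed pairing at 12 weeks gave 0 genes there and Ncoa1 at 0.0066. With the block the exact permutation p of the shares, over 16 assignments, was 0.375 for fibroblasts, 0.875 for macrophages and endothelial cells and 0.25 for granulocytes. It too tests the mean over both times, in which the macrophage differences cancel.

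Leaving out each heart in turn gave gene counts of 0 to 4 in fibroblasts at 24 h, 0 to 2 for the difference and 3367 to 5591 for time; 1 to 3 in macrophages at 24 h, 0 to 33 at 12 weeks, 0 to 3 for the difference and 2778 to 4035 for time; and 1 to 20 in endothelial cells at 24 h, 0 to 5 at 12 weeks, 0 to 11 for the difference and 819 to 1284 for time. List counts were 4 to 13 in fibroblasts at 12 weeks and 6 to 15 for the difference, 5 to 16 in macrophages at 24 h, 8 to 9 at 12 weeks and 7 to 14 for the difference, and 4 to 10 in endothelial cells for the difference. Medians in fibroblasts ranged from -0.384 to 0.035 for dissociation-associated genes at 24 h and from -0.79 to 0.33 at 12 weeks, where unfolded protein response genes ranged from -0.599 to 0.12, activated fibroblast genes from -0.044 to 1.08, neutrophil granule genes from -0.073 to 2.87 and cell cycle genes from -0.504 to 0.057. In macrophages neutrophil granule genes at 12 weeks ranged from -0.232 to 3.19, and for the difference unfolded protein response genes from -0.018 to 0.518 and cardiomyocyte RNA from -0.583 to 0.287. In endothelial cells at 12 weeks unfolded protein response genes ranged from -0.313 to 0.007 and granulocyte RNA from -0.137 to 2.24, and inflammatory cytokines for the difference from -0.057 to 0.608. In fibroblasts Ncoa3 at 24 h ranged from -0.229 to 0.104, and at 12 weeks Tsc22d3 from -0.455 to 1.81, Ncoa1 from -0.181 to 0.209, Ncoa2 from -0.0645 to 0.31, Ncoa3 from -0.675 to 0.103 and S100a9 from -1.004 to 4.23. In macrophages Ncoa3 at 24 h ranged from -0.209 to 0.0774, and at 12 weeks Tsc22d3 from -0.144 to 0.539, Ncoa1 from -0.79 to 0.462, Ncoa2 from -0.523 to 0.0337 and Ncoa3 from -0.828 to 0.0738. In endothelial cells Ncoa3 at 24 h ranged from -0.0814 to 0.409, and at 12 weeks Ncoa2 from -0.433 to 0.605 and S100a8 from -0.528 to 4.40. For shares the limit was the spread between hearts. With 2 hearts per group, leaving out 1 cannot move a share difference by more than this, so the comparison decides nothing about shares.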

Other observations

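In this part the clock test on genes not first noticed and the test without 1 control heart were set before their results were seen; all other tests, and the genes named here, were chosen only after the result was seen. Mural cells, the pericytes and smooth muscle cells around vessels, had a larger share in every drug heart than in any control of the same time: 0.145 ± 0.123% (SD) and 0.568 ± 0.0149% at 24 h, and 0.316 ± 0.132% and 0.633 ± 0.112% at 12 weeks (exact permutation p = 0.0556, 0.333 adjusted over 12 classes; 7 cells in the 24 h controls). With classes from marker UMIs this did not hold: the shares were 6.63% and 5.89% in controls and 4.51% and 5.86% with drug at 24 h, and 7.24% and 6.24% against 5.70% and 8.44% at 12 weeks. In edgeR on cell numbers the log2 ratio was 1.30 (adjusted p = 0.11). Epicardial cells, which cover the heart, were 2.61 ± 0.0991% of control and 5.11 ± 0.229% of drug cells at 12 weeks, and 0.640% and 0.343% at 24 h (exact permutation p = 0.333 over both times). In mural cells at 12 weeks Dcn, a marker of fibroblasts, fell with drug (log2 change -2.16 ± 0.31, adjusted p = 7.13e-04); the libraries hold 23 to 85 of these cells, and RNA carried over from fibroblasts was not measured.

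In the B cell cluster at 12 weeks 60 genes passed, 53 higher and 7 lower with drug. Of those higher, 14 are macrophage markers and 4 are cell cycle genes, among them the complement gene C1qa (2.59 ± 0.32), the macrophage growth factor receptor Csf1r (3.07 ± 0.46) and Lyve1 (3.31 ± 0.52), while the immunoglobulin genes Igkc (-1.79 ± 0.41) and Ighm (-1.56 ± 0.35) fell; the hearts hold 117 and 254 of these cells in controls and 124 and 51 with drug. In an unnamed cluster with the monocyte and dendritic genes Cd74, Ly6c2 and Cd209a, 7 genes passed at 24 h. Spp1 fell (-3.64 ± 0.44, adjusted p = 0.0188), as did Plin2 (-1.28 ± 0.21, adjusted p = 0.0301), Ctsc (-1.27 ± 0.19) and Fxyd7 (-2.51 ± 0.28), and Lefty1 (5.32 ± 0.58, adjusted p = 0.00109), Treml2 (2.11 ± 0.27) and Coro2a (1.76 ± 0.25) rose. In fibroblasts Lefty1 was near absent only in the 24 h controls, and whether these hearts differ in another way that lowers it was not tested. When each cluster was fitted alone at 24 h, 68, 45 and 77 genes passed in fibroblast clusters 0, 2 and 3, 48 and 4 in macrophage clusters 12 and 7, and 3 in endothelial cluster 19. Of 8 clusters, the chaperone Hspa8 (median -0.81) and Plin2 (-1.21) fell in 5 and the translation factor Eif4a1 (-0.76) in 4. The ribosomal protein genes Rpl12 (0.84), Rplp1 (0.68) and Rpsa (0.67) had higher values in 8 of 8 and passed in 3 each. Zfp984 was higher in 5 of 5 clusters that tested it and passed in 3.

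Zinc finger genes beside each other on chromosome 4 were low in both 24 h control hearts, with Zfp979 at 0 and 0 UMIs in those hearts, 117 and 102 in the 24 h drug hearts and 389 to 728 in the 12 week hearts. A drug effect present at both times is argued against, since the median log2 change of the raised genes of the region at 12 weeks was 0.366, and so, for Zfp979, is the authors' setting to 0 of genes seen in few cells, since 55.8 UMIs were to be expected in the smaller control library at the level of the drug hearts; for Gm26624 and Zfp982 this cannot be told apart, with 8.2 expected there for each. A genetic difference of the region between the 24 h control hearts and the others may account for it. It cannot be told apart from a drug effect at 24 h alone: the region had an adjusted p of 0.048 in a first scan, where it ranked 2 and which was 1 of 9 (0.432 when multiplied by 9, a rule set after that p was seen), and of 5.52e-04 in a later scan whose limits were set on the first, and a difference in background would be confounded with the group. In the later scan 5 of 11 tested genes of the region were raised, Zfp991, Gm26624, Zfp982, Zfp979 and Zfp984.

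Clock genes had some of the smallest p between the arms at 12 weeks, though none passed in any class (0.166 was the smallest adjusted p). A different time of day at collection fits, since the index of clock genes other than those first noticed lay above both controls in both drug hearts in 3 of 3 classes, by 1.55 in fibroblasts, 0.884 in macrophages and 0.719 in endothelial cells; the index has no p, and the 3 classes come from the same 4 hearts. The 1 control heart that stands apart is argued against as the cause, since without 12w_control replicate 1 the log2 change of Arntl in fibroblasts was -2.763 against -2.67 with it. A drug that moves the clock the same way at both times cannot be told apart. For this the index was taken over all listed genes, with those first noticed. It lay on opposite sides of the controls at the 2 times in only 1 of 3 classes. In fibroblasts it was -1.27 at 24 h and 2.64 at 12 weeks, and -0.831 and 1.55 without the genes first noticed. An effect of the drug on the clock at 12 weeks alone stays open, as the labels give no hour of collection.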
